A study of Mus musculus with 6 samples.

How the data were processed

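The 6 samples are heart RNA of E10.5 mouse embryos, 3 wild type and 3 Rnd3 knockout, each hybridised as biotin-labelled cRNA to an Affymetrix whole-genome mouse expression array. Samples were grouped by the genotype in their labels. The series' design text speaks of littermate pairs, but no label says that a replicate number marks a litter, nor whether an array holds 1 heart or several. The p-values therefore measure the spread between these arrays.

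The deposited values are signal intensity per probe set on a linear scale, made with MAS5 and Affymetrix Expression Console per the submitters' processing notes. Their versions and settings are not given in the sources used here. MAS5 compares perfect-match with mismatch probes and scales each array to a target. In the values, the mean of every array after trimming 2% at each end was 500, and no further scaling between arrays was applied in the main analysis. Dim probe sets are noisy on this scale. Detection calls were not used here, so a low-signal limit was set instead at each array's 40th percentile over all probe sets that are not controls, which came to 44.5 to 52.8. This limit is a working choice, not a measured background. Where all 3 arrays of a group lay below it, a bound is given as "at least N-fold", the mean log2 signal of the bright group against the dim group's mean of, per array, the higher of the limit and the probe set's own signal.

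The 64 control probe sets were left out. In the platform's annotation 34945 of the other 45037 had 1 gene symbol, 932 had several and 9160 were unnamed here. Of the named ones, 34741 were matched by gene identifier to a RefSeq gene table, which updated 0 symbols. The same table gave the gene lengths used to match random lists. Values were taken to log2. For each of 18193 genes the probe set with the highest mean was used, 9010 genes having more than 1, and a gene was tested if that probe set was above the limit on at least 3 of the 6 arrays, which left 12712. Ddx3y, on the sex-linked list, was not analysed here.

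Differential expression was tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend), KO minus WT, with Benjamini-Hochberg adjustment and a threshold of 0.05. "Rose" and "fell" are used of genes past it, and errors of log2 fold changes are limma's standard errors. Gene lists were tested with camera (preset correlation 0.01, two-sided), with camera again using a correlation estimated from these arrays, and with fry, each adjusted over 38 lists. Camera sets a list against all other genes, so its direction can differ from the sign of the median.

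The 38 lists were fixed before the data were examined, as were the design, the naming rule and the alternatives, apart from the sex covariate. They cover sarcomere, calcium handling, beta-adrenergic and cAMP-PKA signalling, ion channels and gap junctions, cardiac transcription factors, chamber markers, actin cytoskeleton and SRF targets, Hippo-YAP, Notch, Wnt, TGF-beta and BMP, hypoxia, glycolysis, oxidative phosphorylation, fatty acid oxidation, cholesterol synthesis, both cell cycle phases, p53 targets, apoptosis, NF-kB, protein stress, immediate early genes, extracellular matrix and cytosolic ribosomal proteins. The cell type lists cover endothelium, cushion mesenchyme, second heart field, epicardium, erythroid cells, macrophages, platelets, liver and yolk sac endoderm, foregut epithelium, neurons, neural crest and skeletal muscle precursors. A further list of sex-linked genes served as a sample check. The result of 1 of the 38 lists is not reported here.

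The text names Rnd3, the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold whose groups did not overlap (gene models without an official name were skipped), up to 4 members of each list with the smallest p, and the sex-linked genes. Outside this rule it names every oxidative phosphorylation gene that rose and the endoderm marker Ttr. Members of gene families chosen after the results were seen are named as well.

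The procedure was tested on simulated data with the real genes' means and spreads, 12712 genes and 200 changed genes in each of 10 runs. It recovered 55.9% of genes changed 1.5-fold, 83.9% of those changed 2-fold and 93.8% of those changed 4-fold, with 6.41% false calls, and at most 5 calls in runs without change. A list shifted by 0.15 on the log2 scale was found in 10 of 10 runs, with 0.2 other lists called per run (fatty acid oxidation not counted). Simulated genes varied independently and with the same spread in both groups. The runs therefore do not show how the tests behave where genes vary together, as on the real arrays. Alternatives covered normalization, centring, a floor on low values, the filter, the choice of probe set, the variance model, array weights, a replicate block, thresholds, the list test and leaving out each array. A covariate for the sex of the tissue was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.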

Results

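Gene expression was measured in hearts of mouse embryos at E10.5, a day of mid-gestation when the looped heart tube is building its chambers. The 3 wild-type (WT) and 3 knockout (KO) arrays, 6 in all, came from embryos of the C57BL/6N background. The knockout removes Rnd3, also called RhoE, by a gene trap, an insertion that interrupts the transcript. Rnd3 encodes a protein that binds GTP without hydrolysing it and restrains the kinase ROCK1. Per the series' design text, global knockout embryos die in mid-gestation from about this stage on, and the arrays compare the heart transcriptome just before that. Each array gave a MAS5 signal for 45037 probe sets besides controls, of which 34945 carry the symbol of exactly 1 gene, and 12712 genes were tested. For arrays, their number, 3 per group, limits the precision. Log2 signals of these genes correlated between arrays of a group at r = 0.982 to 0.983 in WT and 0.975 to 0.978 in KO. KO array 1 correlated more closely with every WT array (r = 0.979532 to 0.98097) than with KO array 2 (0.975871) or 3 (0.978325). The WT arrays correlated best with one another, and KO arrays 2 and 3 best with KO array 1. At most 2 probe sets had the same value on any 2 arrays.

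The knockout was visible in Rnd3 itself. Its brightest probe set read 909, 954 and 862 in the WT hearts and 5.89, 12.3 and 121 in the KO hearts, a log2 fold change of -5.46 (SE 0.81, limma adjusted p = 0.0344, n = 3 per group). KO arrays 1 and 2 lay below the low-signal limit, set at each array's 40th percentile, while KO array 3 lay above it. The other Rnd3 probe set read 238, 209 and 180 in WT and 2.24, 46.4 and 32.3 in KO, below the limit on all 3 KO arrays and at least 4.29-fold lower. Where these probe sets lie relative to the trap insertion was not analysed here. The Rnd3 call missed the threshold without the filter on dim probe sets (adjusted p = 0.0518) and when the gene's probe sets were averaged (-4.63, adjusted p = 0.0971). It was also missed without the intensity trend in the variance (adjusted p = 0.206) and when WT array 1, 2 or 3 was left out (adjusted p = 0.15, 0.170 and 0.114).

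**Figure D1:**
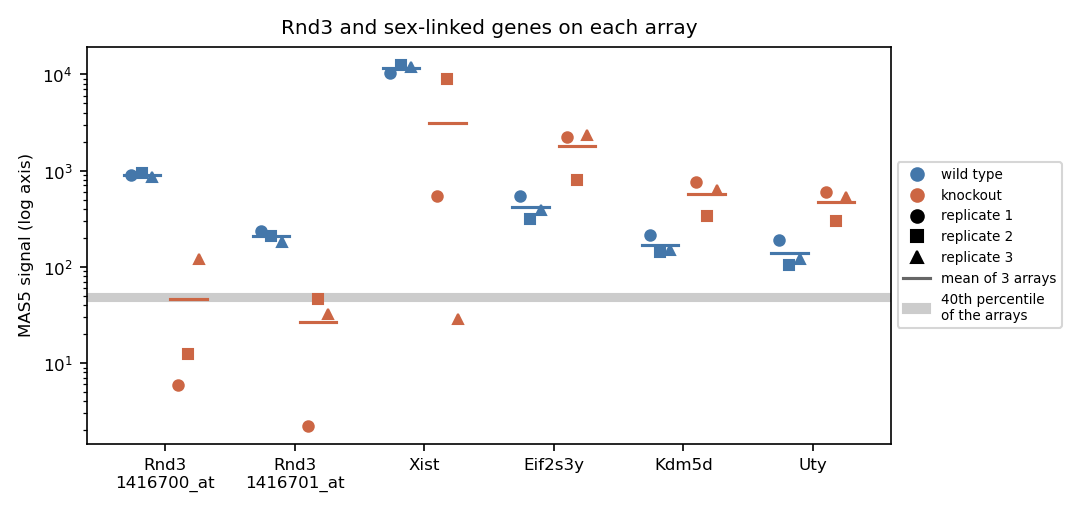
MAS5 signal (log axis) of both Rnd3 probe sets, Xist and 3 Y-linked genes on each of the 3 wild-type (blue) and 3 knockout (red) arrays; marker shape gives the replicate number, short lines are means of 3 arrays and the grey band is the range of the arrays' 40th percentiles. All 3 KO signals of Rnd3 lie below all 3 WT signals, and the X-linked transcript Xist reads 539 and 28.4 on KO arrays 1 and 3 against 8884 on KO array 2.

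The KO and WT arrays differed modestly in many genes of the E10.5 heart, though the number past the threshold rested on the processing. Xist, which marks female tissue, was high on all WT arrays but low on KO arrays 1 and 3. Effects of the genotype therefore cannot be told apart from a different share of male tissue. Among the genes that rose in KO, Kcne1, a regulatory subunit of the slow delayed-rectifier potassium channel, went from a signal of 264 ± 64.7 in WT to 527 ± 110 in KO (SD, n = 3 per group). Another, dimmer Kcne1 probe set went the other way, from 193 ± 68.8 in WT to 135 ± 21.4 in KO. Ntn1, which encodes the secreted guidance cue netrin-1, went from 788 ± 50.3 to 1847 ± 627, and Tm4sf1, a tetraspan membrane protein of endothelial and other cells, from 522 ± 77.8 to 1153 ± 323. Among the genes that fell, Tbx3, a transcriptional repressor of the cardiac conduction system, went from 689 ± 73.4 to 392 ± 43.5. Malat1, an abundant nuclear long noncoding RNA, went from 10959 ± 4514 to 3668 ± 787.

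Of the 12 genes named for their rises, 11 were above the low-signal limit on some arrays of both groups, with log2 fold changes from 0.98 to 1.99. The other, Slco2b1, an organic anion transporter, was below the low-signal limit on all 3 WT arrays and at 133 ± 54.3 in KO, at least 2.49-fold higher (adjusted p = 0.0360). The Y-linked genes Eif2s3y, Uty and Kdm5d were higher by 1.99 (SE 0.35), 1.75 (SE 0.28) and 1.73 (SE 0.27), and the sex of the tissue on each array is given with the sex-linked genes. Over 16 alternatives their lowest values were 0.43, 0.74 and 0.65. Lyz2, the lysozyme gene of macrophages, rose by 1.38 (SE 0.25, adjusted p = 0.0374), and Lgals9, the lectin galectin-9, by 1.35 (SE 0.28, adjusted p = 0.0487). Ntn1 (1.17, SE 0.21), Tm4sf1 (1.12, SE 0.19), the platelet chemokine gene Ppbp (1.02, SE 0.22) and Kcne1 (1.01, SE 0.20) followed, with adjusted p from 0.0360 to 0.049997. Mrpl33, a protein of the large mitochondrial ribosomal subunit, had the lowest p of all genes (0.99, SE 0.09, adjusted p = 0.00571), with signals of 2203 ± 64.9 in WT and 4377 ± 466 in KO. Commd3, of the COMM domain family, rose by 0.98 (SE 0.18, adjusted p = 0.0360).

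Among the genes named for their falls, only a bound can be given for Habp2. This gene, a hyaluronan-binding serine protease made by the liver, read 87.0 ± 16.3 in WT and was below the low-signal limit on all 3 KO arrays, at least 1.78-fold lower (adjusted p = 0.0389). Alb, serum albumin, changed by -1.97 (SE 0.42, adjusted p = 0.049997), with 2 of the 3 KO arrays below the limit. Malat1 changed by -1.52 (SE 0.24, adjusted p = 0.0344). The other 8 named genes, with log2 fold changes from -0.91 to -0.74, were the fatty acid desaturase gene Scd1 (-0.91, SE 0.18), Pank3 of coenzyme A synthesis (-0.89, SE 0.12), the ribosomal protein gene Rpl12 (-0.85, SE 0.17), the small nucleolar RNA host gene Snhg3 (-0.84, SE 0.13) and Timm44 of mitochondrial protein import (-0.83, SE 0.14). Tbx3 (-0.81, SE 0.13), Pcyox1l (-0.75, SE 0.16) and Safb2 (-0.74, SE 0.14) completed the list, with adjusted p over these 8 genes from 0.0321 to 0.049977. With a gene's probe sets averaged, none of the 24 genes passed. Among genes for which more than a bound can be given, those over 1.5 times smaller there were Tbx3 (-0.20, adjusted p = 0.808), Scd1 (-0.49), Pank3 (-0.52), Safb2 (-0.48), Kcne1 (0.27) and Tm4sf1 (0.65), and Mrpl33 reversed (-0.30). The average also takes in probe sets too dim to be tested on their own. For Tbx3 these had 0.33 and 0.58, while its tested probe sets had -0.81, -0.55 and -0.54. All probe sets of Scd1, Pank3, Safb2, Kcne1 and Mrpl33 were tested on their own, so their averages hold no such dim probe sets. With every probe set tested on its own, 7 of the 24 missed the threshold, namely Alb, Scd1, Rpl12, Pcyox1l, Lgals9, Ppbp and Kcne1 (adjusted p from 0.0548 to 0.0625). Rpl12 has near-identical pseudogenes and Lyz2 a close paralog, Lyz1, so their signals are less certain. Among the 24 genes and Xist, 15 had 25 further tested probe sets, and 23 of these had the same sign. The exceptions were a dim Mrpl33 probe set (-1.58) and a Kcne1 probe set (-0.47). The count is by sign alone and includes values near 0, such as a Scd1 probe set at -0.07 and a Pank3 probe set at -0.15.

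**Figure D2:**
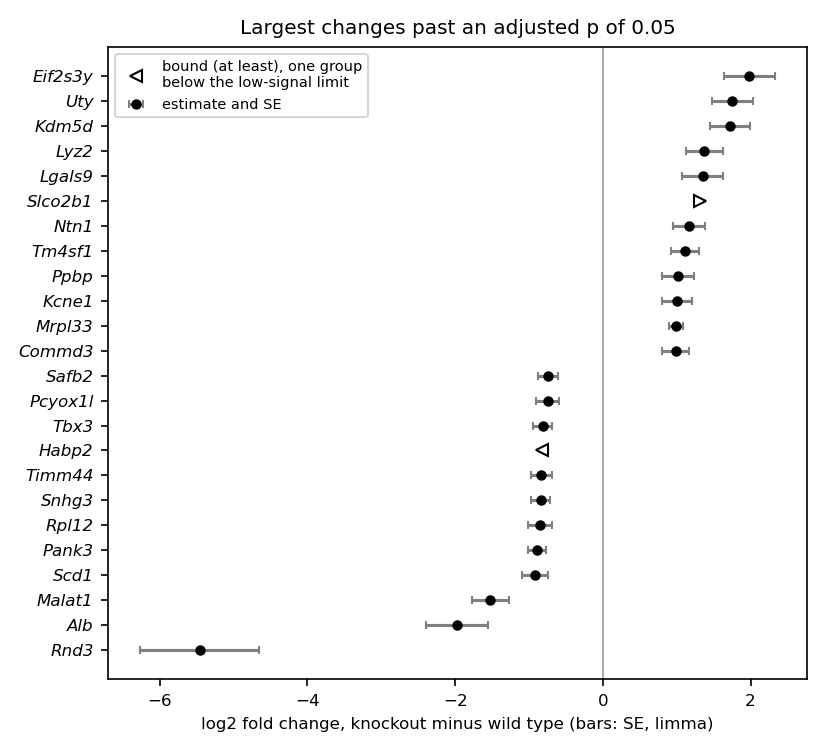
Log2 fold change, KO minus WT, of the 12 named genes with the largest rises and the 12 with the largest falls among genes past an adjusted p of 0.05 (limma); points are estimates from 3 arrays per group and bars their standard errors, and open triangles are bounds for Slco2b1 and Habp2, which lie below the low-signal limit on all arrays of 1 group. Rnd3 has the largest change, -5.46, and the longest bar, 0.81.

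In all, 162 of 12712 genes passed an adjusted p of 0.05, 100 higher and 62 lower in KO, with a median size of 1.5-fold among the higher and 1.49-fold among the lower ones. Only 14 of them had a fitted change over 2-fold, 10 higher and 4 lower, and for Habp2 among these the bound is 1.78-fold. The 10 include the Y-linked genes Eif2s3y, Uty and Kdm5d, and the 4 include Rnd3 itself. The groups did not overlap for 3348 genes, or 26.3%, against 10% by chance, and 2580 genes had an unadjusted p below 0.05. With each array centred on its median, 312 genes passed, of which 253, or 81.1%, were higher and 59 lower, against 61.7% higher without centring. The count rested on the processing: it was 1 without the filter on dim probe sets, 0 with a gene's probe sets averaged and 1 without the intensity trend. It was 0, 0 and 4 without WT array 1, 2 or 3, and 916, 65 and 2 without KO array 1, 2 or 3.

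Of 70 tested subunits of oxidative phosphorylation, 6 rose, none fell and 64 did not pass, or 15 up and 1 down adjusted over the list alone, and 56 had a positive log2 fold change. The 6 were Uqcrfs1, the Rieske protein of complex III (0.73, SE 0.09), Uqcrh, also of complex III (0.56, SE 0.08), Sdhd of complex II (0.58, SE 0.09), Ndufa4 of the respiratory chain (0.46, SE 0.08), Ndufs5 of complex I (0.43, SE 0.08) and Atp5l of the ATP synthase (0.40, SE 0.08). Signals of Uqcrfs1 went from 5635 ± 36.2 to 9397 ± 1161. The median of the list was 0.12, and limma's camera test with its preset inter-gene correlation of 0.01 passed (adjusted p = 8.89e-09, higher). The call was lost with the correlation taken from the data (adjusted p = 0.995 with an estimated correlation). With the Xist share of each array as a sex covariate the list's median was 0.06 (adjusted p = 0.0426). The fit with this covariate, here and below, rests on KO array 2. That array has a weight of 1.26 against -0.09 and -0.17 for KO arrays 1 and 3. Of 29 genes of fatty acid oxidation and uptake, Etfa, the alpha subunit of the electron transfer flavoprotein, rose (0.64, SE 0.13, adjusted p = 0.0454), 28 did not pass, and 8 were up and 1 down adjusted over the list alone. That list also passed (median 0.12, camera adjusted p = 0.00348; adjusted p = 0.995 with an estimated correlation); its dehydrogenase gene Acadl had 0.47 and its hydratase gene Echs1 0.47, while the carnitine carrier gene Slc25a20 had -0.38. With the sex covariate it missed the threshold (median 0.12, adjusted p = 0.121). Glycolysis (median 0.01 and mean -0.02 over 15 genes, adjusted p = 0.865) and cholesterol synthesis (median -0.10 over 20 genes, adjusted p = 0.759) did not pass and had no member past the test over all genes, though cholesterol synthesis had 2 up and 2 down adjusted over the list alone. Glycolysis passed as lower with the sex covariate (adjusted p = 0.0132) and as higher without KO array 2 (adjusted p = 0.0317). The ratio of 3' to 5' Gapdh probe signal, a sign of RNA integrity, was 1.11 ± 0.0175 in WT and 0.969 ± 0.0274 in KO, with no overlap between the groups; that of Actb was 2.52 ± 0.147 and 2.40 ± 0.164.

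**Figure D3:**
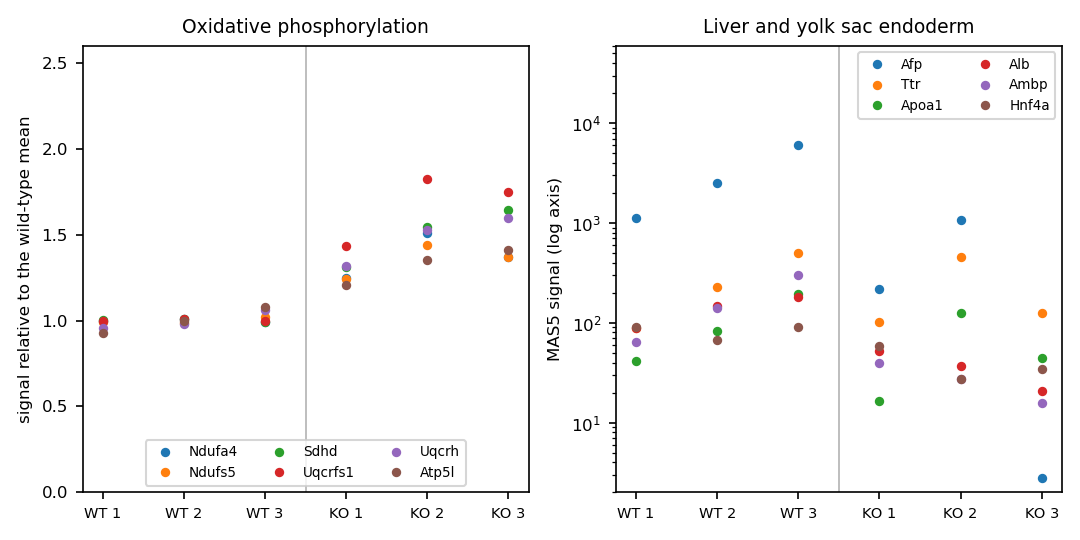
Left, signals of the 6 oxidative phosphorylation genes that rose, on each array, divided by the gene's WT mean; right, MAS5 signals (log axis) of 6 liver and yolk sac endoderm markers on each array. The largest rise on the left is that of Uqcrfs1, and on the right Afp spans 1116 to 6054 in WT and 2.78 to 1074 in KO.

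Among chamber and conduction genes, the natriuretic peptide gene Nppb rose by 0.97 (SE 0.17), from 4657 ± 207 to 9407 ± 2598, and the ventricular transcriptional co-regulator gene Cited1 by 0.92 (SE 0.17). These were the 2 of 19 chamber markers past the test, with 6 up and 0 down adjusted over the list alone; Slit2 had 0.57 and Ankrd1 0.28. The list had the highest median of the 38, 0.17, and missed the threshold (camera adjusted p = 0.0571). It passed as higher without the filter (adjusted p = 0.0357), with the sex covariate (adjusted p = 0.0462) and with the replicate number as a block. The same held without WT array 1 or 3 or KO array 1 or 3 (adjusted p = 0.0447, 0.0486, 0.0424 and 0.00944). Of 31 cardiac transcription factors only Tbx3 passed, and Mef2c had -0.39, Irx4 0.47 and Gata6 0.25 (list median -0.06, adjusted p = 0.385; lower with the sex covariate, adjusted p = 0.0426). Of 21 ion channel and gap junction genes only Kcne1 passed, with Kcnh2 at -0.32 (median 0.05, adjusted p = 0.539). Of 31 sarcomere genes only Smpx, a small muscle protein gene, passed (0.45, SE 0.08), and Myh6, the alpha myosin heavy chain, had -0.25 (2 up adjusted over the list alone, median -0.0043, mean 0.02, adjusted p = 0.828). None of 30 calcium handling genes passed (median -0.03, adjusted p = 0.759), among them the channel gene Cacna1d (-0.53), Casq1 (-0.63), Jph2 (-0.36) and the ryanodine receptor gene Ryr2 (-0.26). None of 39 genes of beta-adrenergic and cAMP-PKA signalling passed over all genes and 3 were down adjusted over the list alone, namely Akap5 (-0.57), Pde3b (-0.41) and Pde7a (-0.43) (median -0.06, adjusted p = 0.865).

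Of 36 actin cytoskeleton genes Myh9, a nonmuscle myosin heavy chain, fell (-0.46, SE 0.09), and 3 were down adjusted over the list alone, with Tpm2 at -0.47 and Tpm4 at -0.29 (median -0.07, adjusted p = 0.305). Yap1, the transcriptional effector of the Hippo pathway, fell (-0.41, SE 0.08) as 1 of 25 Hippo genes, and its target Ccn1 had -0.43 (median -0.01, adjusted p = 0.972). In Wnt signalling the transcription factor gene Lef1 (-0.61, SE 0.12) and the co-receptor gene Lrp6 (-0.47, SE 0.10) fell as 2 of 32, and 1 was up and 3 were down adjusted over the list alone (median -0.16, adjusted p = 0.214). Bmp4, a secreted ligand, fell (-0.50, SE 0.09) as 1 of 38 genes of TGF-beta and BMP signalling, with Bmp2 at -0.55 (median -0.09, adjusted p = 0.494). None of 28 Notch genes passed, with Hey1 at -0.44 (median -0.11, adjusted p = 0.435).

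Of the cell cycle genes, Top2a, the mitotic topoisomerase, fell (-0.33, SE 0.07) as 1 of 39 genes of G2 and M phase, and 3 were down adjusted over the list alone (median -0.09, adjusted p = 0.0946). That list passed as lower with quantile normalization (adjusted p = 0.0163), without the filter (adjusted p = 0.0357), with the sex covariate (adjusted p = 0.000149) and without KO array 1 or 3 (adjusted p = 0.0288 and 0.0219). Ccne2, a cyclin of S phase entry, rose (0.50, SE 0.10) as 1 of 44 genes of G1 and S phase (2 up and 2 down adjusted over the list alone, median -0.02, test direction higher, adjusted p = 0.987). Among 35 genes of the unfolded protein and amino acid stress response, Herpud1, of protein degradation at the endoplasmic reticulum, rose (0.67, SE 0.11), with 1 up and 3 down adjusted over the list alone, the latter Hyou1 (-0.48), Aars (-0.62) and Shmt2 (-0.44) (median -0.14, adjusted p = 0.0946). That list passed as lower with quantile normalization (adjusted p = 0.0246), without the filter (adjusted p = 0.0357), with the sex covariate (adjusted p = 0.00438) and without KO array 3 (adjusted p = 0.0225). No member passed over all genes among p53 targets (26 genes, 1 down adjusted over the list alone, median 0.02, mean -0.02, test direction higher, adjusted p = 0.865), apoptosis regulators (27 genes, -0.01, adjusted p = 0.828) or NF-kB and inflammation genes (23 genes, -0.04, adjusted p = 0.865). The same held for HIF and hypoxia targets (34 genes, median -0.06, adjusted p = 0.987), where Gbe1 (0.85) and Bhlhe40 (0.63) were up adjusted over the list alone, and for immediate early genes (23 genes, median -0.02, mean 0.00348, adjusted p = 0.987). Extracellular matrix genes (39 genes, median -0.05, adjusted p = 0.987) and cytosolic ribosomal proteins (35 genes, 1 up and 1 down adjusted over the list alone, median 0.01, adjusted p = 0.214) had no member past the test either. The ribosomal list passed as higher with median centring (adjusted p = 0.0352) and without KO array 2 or WT array 3 (adjusted p = 0.0317 and 0.0116). Where no count adjusted over the list alone is given for a list, it equals the count over all genes.

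Markers of other cell types were compared in the same way. All 14 tested markers of liver and yolk sac endoderm were lower in KO, with a median of -0.83, and the list passed (camera adjusted p = 0.00272; adjusted p = 0.995 with an estimated correlation). Alb alone passed over all genes, and 4 were down adjusted over the list alone. The list missed the threshold with a stricter filter, which left 6 of its genes (median -0.42, adjusted p = 0.202), and with the sex covariate (median -0.19, adjusted p = 0.964). Ambp, a plasma protein precursor, read 169 ± 121 in WT and was below the limit on all 3 KO arrays, at least 2.89-fold lower (adjusted p = 0.0554), and Afp, alpha-fetoprotein, read 3222 ± 2548 in WT and 431 ± 567 in KO (adjusted p = 0.125). Macrophage and leukocyte markers had a median of 0.11 over 17 genes (adjusted p = 0.214), with Lyz2 past the test and Lyz1 at 0.63. Megakaryocyte and platelet markers had 0.11 over 16 genes (adjusted p = 0.230), with Ppbp past the test and Pf4 at 0.37. The macrophage list passed as higher with the sex covariate (adjusted p = 0.000947) and without KO array 3 (adjusted p = 0.0219), and the platelet list without KO array 2 or WT array 1 (adjusted p = 0.0317 and 0.0447).

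The remaining cell type lists did not pass, except that with 1 array left out the foregut list passed as lower without WT array 1 (adjusted p = 0.0447) and the erythroid list as higher without KO array 3 (adjusted p = 0.0219). Medians were 0.04 for 34 endothelial and endocardial genes (adjusted p = 0.421), -0.11 for 26 genes of cushion and outflow mesenchyme (adjusted p = 0.865), -0.07 for 17 epicardial genes (adjusted p = 0.828) and 0.03 for 24 primitive erythroid genes (adjusted p = 0.435). They were -0.35 for 15 genes of the second heart field and pharyngeal mesoderm (adjusted p = 0.313), with Isl1 at -0.52, and -0.37 for 15 genes of foregut and surface epithelium (adjusted p = 0.305), with Krt18 at -0.44. Of 15 neural genes Crmp1, a neuronal cytoskeleton regulator, fell (-0.73, SE 0.15; list median -0.12, adjusted p = 0.987). Neural crest genes had -0.07 over 10 genes, with the test in the higher direction (adjusted p = 0.865), and skeletal muscle precursor genes -0.10 over 7 genes (adjusted p = 0.865). Across all 38 lists, 3 passed with the preset correlation and 0 with an estimated one, and 9 other groupings of the 6 arrays gave 3 to 11 such lists each. The sign of the median turned under quantile normalization for the glycolysis, apoptosis, NF-kB and immediate early lists. Median centring shifted all lists upward by the same amount. It turned the sign for the sarcomere, calcium handling, Hippo, G1 and S phase, apoptosis, NF-kB, immediate early and extracellular matrix lists, whose medians lay just below 0.

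**Figure D4:**
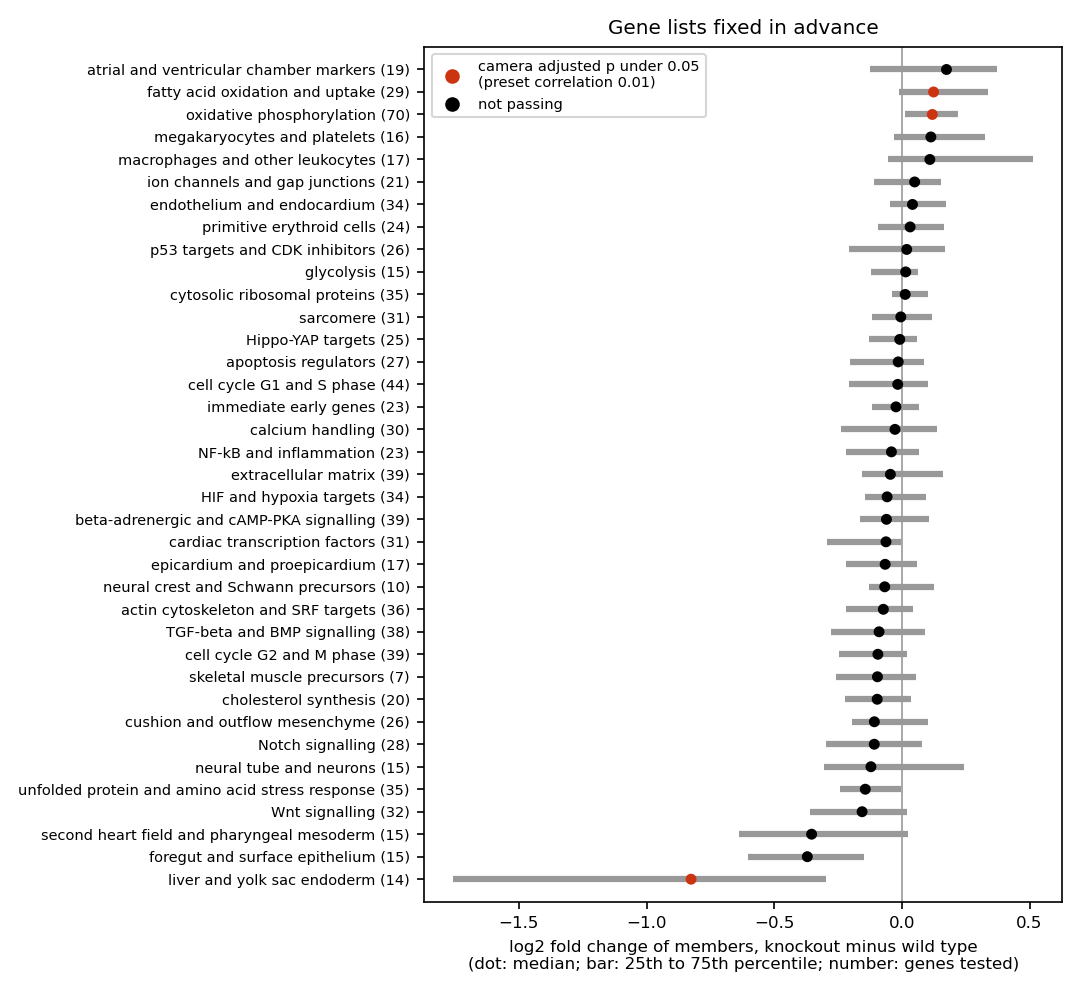
Median (dot) and 25th to 75th percentile (bar) of the members' log2 fold changes, KO minus WT, for the gene lists described in the text, with the number of genes tested after each name. Red dots mark the 3 lists past a camera adjusted p of 0.05 with the preset correlation of 0.01, with medians of 0.12, 0.12 and -0.83.

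The arrays also differed in sex-linked transcripts. Xist, the noncoding RNA of the inactive X chromosome, read 10251, 12474 and 11878 on the WT arrays and 539, 8884 and 28.4 on the KO arrays (log2 fold change -4.48, SE 1.44, adjusted p = 0.120). Eif2s3y, on the Y chromosome, read 551, 312 and 385 on the WT arrays and 2214, 793 and 2339 on the KO arrays. With the Xist share of each array as a covariate, 819 genes passed, 306 higher and 513 lower, of which 107 were among the 162.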

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

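All alternatives here were planned before the data were examined, except the sex covariate, which was chosen after seeing the data. The count of 162 changed genes moved to 312 with median centring, 1 without the filter on dim probe sets, 256 with a stricter filter, 0 with a gene's probe sets averaged (1758 genes at an unadjusted p under 0.05), 1 without the intensity trend and 542 with array weights. It was 805 at an adjusted p of 0.10, 79 with a 1.5-fold minimum and 819 with the sex covariate, and 0 to 916 when 1 array was left out. It stayed within 1.5 times with quantile normalization (207) and a floor on low values (177). With every probe set on its own, 163 of 27404 probe sets passed, from 129 genes, and 82 of the 162 genes passed with their own probe set. In every setting that tests genes, all called genes with a value kept their direction, except that 158 of 162 did so with probe sets averaged. The stricter filter tested 158 of the 162. Most of these settings could not turn a direction, so kept direction in them tests nothing. The filter, the trend and the block leave the fold change as it is. Since the groups did not overlap for any of the 162, leaving out or weighting arrays could not reverse a gene either. The cause of the changes in count was not tested, but many adjusted p lie close to the threshold, with 805 below 0.10.

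Rnd3 stayed lower throughout. It missed the threshold without the filter (-5.46, adjusted p = 0.0518), with probe sets averaged (-4.63, adjusted p = 0.0971) and without the trend (-5.46, adjusted p = 0.206). Its log2 fold change ranged from -6.74 to -4.56 when 1 array was left out, and its adjusted p over 17 alternatives from 2.26e-06 to 0.206.

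The count of 3 shifted lists became 0 with an estimated correlation (1 list at an unadjusted p under 0.05), 0 with fry (6 lists), 5 with quantile normalization, 6 without the filter and 7 with the sex covariate, whose fit rests on KO array 2, and 3 to 8 when 1 array was left out. The 7 with the sex covariate were oxidative phosphorylation and, newly, G2 and M phase (lower, adjusted p = 0.000149), macrophages (higher, 0.000947), protein stress (lower, 0.00438), glycolysis (lower, 0.0132), cardiac transcription factors (lower, 0.0426) and chamber markers (higher, 0.0462). Quantile normalization added G2 and M phase and protein stress, the missing filter these and chamber markers, and median centring cytosolic ribosomal proteins (higher, adjusted p = 0.0352). Fatty acid oxidation missed the threshold with the sex covariate (adjusted p = 0.121), as did the endoderm list (adjusted p = 0.964) and, with the stricter filter, again the endoderm list (adjusted p = 0.202). Over 18 alternatives adjusted p ranged from 3.80e-14 to 0.995 for oxidative phosphorylation, 0.000108 to 0.995 for fatty acid oxidation and 1.66e-05 to 0.995 for the endoderm list. Among 380 values of the named genes under alternatives, 197 kept direction and side of the threshold, 179 kept direction but missed it, 2 newly passed and 2 reversed. Of the 380, 144 came from leaving out 1 array, where direction could not turn because the groups of these genes did not overlap. Mrpl33 reversed to -0.30 with probe sets averaged, since its dim probe set went the other way, and Xist to 1.44 with the sex covariate, which is made from Xist.

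With the replicate number as a block, 189 genes and 4 lists passed, the added list being chamber markers (higher, adjusted p = 0.0396), and Rnd3 remained past the threshold (adjusted p = 0.00196). Deviations of same-numbered arrays in both groups correlated at r = 0.015 to 0.057 over genes (n = 3 pairs), all under 0.1. Those of differently numbered arrays correlated at r = -0.037 to 0.021. Of the arrays 2 of 3 in WT and 2 of 3 in KO correlated best with their own number, with 1 of 3 pairs best from both sides. Since every r was under 0.1, a working bound, the main fit does not pair the arrays by number. Such low values do not exclude litter pairs. Signal over background limits genes near the low-signal limit, whose log2 values vary most.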

Other observations

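The tests of other groupings for the gene and list counts, of the sex covariate, of endoderm admixture and of mixed sexes, and all gene families named here, were chosen after the results were seen. The matched random lists and the other groupings for oxidative phosphorylation were planned beforehand.

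Of 76 tested genes for proteins of the mitochondrial ribosome, nuclear-encoded subunits that translate the mitochondrial genome, 6 rose and 0 fell, and 55 had a positive log2 fold change, with a median of 0.14 (0.13 with quantile normalization, 0.19 with median centring). Mrpl33 (0.99) led, followed by Mrps18c (0.62, SE 0.10), Mrpl14 (0.58, SE 0.11), Mrpl34 (0.57, SE 0.11), Mrpl23 (0.52, SE 0.09) and Mrpl32 (0.42, SE 0.09). Camera gave an adjusted p = 2.07e-08 over 10 families, and adjusted p = 0.385 with an estimated correlation. Because the families were chosen after the results were seen, the adjusted p given for them do not account for that choice. The families were not set against random lists matched on signal and gene length. Of 10 COMMD genes, whose proteins take part in endosomal sorting, Commd3 (0.98) and Commd1 (0.47, SE 0.09) rose (median 0.30, adjusted p = 0.00653; adjusted p = 0.385 with an estimated correlation). Of 37 proteasome subunits Psmd8 rose (0.53, SE 0.10; median 0.10, adjusted p = 0.000497; adjusted p = 0.385 with an estimated correlation). Of 21 mitochondrial import genes Timm21 (0.68) and Timm17a (0.46) rose while Timm44 (-0.83) fell (median 0.12, adjusted p = 0.0109; adjusted p = 0.385 with an estimated correlation).

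Mitochondrial carriers (39 genes, median 0.07, adjusted p = 0.109), Snhg genes (14 genes, -0.19, adjusted p = 0.144), hnRNP genes (19 genes, -0.03, above 0 with median centring, adjusted p = 0.244), Zfp genes (306 genes, -0.08, adjusted p = 0.443) and Ddx and Dhx helicases (48 genes, -0.11, adjusted p = 0.390) did not pass as families.

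Oxidative phosphorylation genes had a median log2 fold change of 0.119 over 70 genes. A trend with signal level and gene length alone is argued against, since random lists matched on both rarely reached so high a median. The list's median lay at percentile 99.94 of 10000 such lists, whose central 95% ended at 0.0873 and whose highest was 0.128. The random lists were not matched on the variation that the list's genes share (estimated correlation 0.357). They cannot decide whether the trend and shared variation together suffice. These lists had a median of 0.0358, against -0.0396 over all genes, so part of the list's distance from other genes goes with signal and length. Other groupings of the 6 arrays leave chance open, since 10 splits cannot give a share under 0.05; 2 of 10 splits reached a median of this size, the real one included, with 0.124 the highest other. With the sex covariate the median was 0.0650, a ratio of 0.545 (95% interval 0.419 to 0.936). The interval comes from resampling the list's genes and carries no spread between arrays. A different share of male tissue cannot be told apart from the genotype for this list, because the fit with the covariate rests on KO array 2.

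All 14 liver and yolk sac endoderm markers were lower in KO, and 0 of them are on another list. A candidate explanation is that different amounts of neighbouring endoderm were dissected with the hearts. Within groups the markers deviated together, as varying admixture requires. Their mean pairwise correlation was 0.186, at percentile 98.88 of 10000 matched random lists (95th percentile 0.122). The same measure was higher for primitive erythroid (0.419) and epicardial markers (0.286) and lower for endothelial ones (0.0701). The shared deviation of the endoderm markers therefore cannot tell admixture from other shared variation. The markers did not all move alike: Afp read 1116, 2496 and 6054 in WT and 216, 1074 and 2.78 in KO, while Ttr read 89.3, 229 and 501 in WT and 103, 460 and 125 in KO. Only 5 of the 14 were above the low-signal limit on all arrays, the list's median was -0.19 with the sex covariate, and less endoderm in the knockout embryos themselves stays open, untested.

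Xist and the 3 Y-linked genes were all above the low-signal limit on 5 of 6 arrays, although Xist marks female and the Y-linked genes male tissue. Relative to KO arrays 1 and 3, which had the highest signals, the Y-linked genes averaged 29.5%, 17.6% and 19.9% on the WT arrays and 45.2% on KO array 2. The largest SD over genes was 0.314 (log2), against 0.613 between these 4 arrays. The ratio was not constant, since Eif2s3y was the lowest on each of them, at 34.8% on KO array 2 against 48.0% for Kdm5d and 52.8% for Uty. Tissue of both sexes on an array, for example from pooled hearts, may explain the pattern. The SD comparison cannot tell it from other sources of signal on these probe sets, which were not tested. As a source of the gene changes, a different share of male tissue stays open, although the covariate changed log2 fold changes of the 159 called genes off the Y chromosome by a median ratio of 1.25. It cannot be told apart from the genotype, because among the KO arrays only array 2 has much Xist signal (71.2% of the highest). The fit with the covariate therefore rests on this array, with a weight of 1.26 against -0.09 and -0.17 for KO arrays 1 and 3.

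The real split of the arrays gave 162 changed genes and the highest other split 1, so 1 of 10 splits gave as many; 10 splits cannot give a share under 0.05. For lists the real split gave 3 and the highest other 11, and 10 of 10 splits gave at least as many. Oxidative phosphorylation passed in 4 of the 9 other splits, the endoderm list in 3 and fatty acid oxidation in 2.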
